A study of Mus musculus with 16 samples.

How the data were processed

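RNA was sequenced from immortalized mouse embryonic fibroblasts (iMEFs) of 2 lines. Both carry a doxycycline-responsive transactivator and a Cre recombinase under its control. The exp line has 2 floxed copies of Sdhc (fl/fl) and the ctl line has 1 floxed and 1 wild-type copy (fl/wt). Sdhc encodes a membrane subunit of succinate dehydrogenase, an enzyme of the citric acid cycle and the respiratory chain. Per the labels' protocols, doxycycline was given at 1 µg/mL. Libraries came from 6 days (0, 5, 9, 12, 16 and 20) of each line, with 3 biological replicates per line at day 16 and 1 library at each other day, 16 libraries in all. Samples were grouped by the line and day in their titles. There is 1 line per genotype, so line and genotype cannot be separated by any comparison made here.

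The values analysed are FPKM per gene as deposited by the authors, 1 file per library with 24485 gene IDs, and the labels do not say how replicates of the same number are related. The submitters' processing notes name the mouse genome build mm9 and Bowtie2 2.2.3; the counting tool, annotation and strand setting are not given in the sources used here. Of the gene IDs, 24416 were matched to a symbol through a table of gene names. Gene coordinates are those of a reference annotation on the same assembly and are 1-based. A gene-level FPKM does not show which exons were read, and the labels do not say which part of Sdhc is flanked by loxP sites, so reads from the remainder of the transcript stay in the Sdhc value.

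Within a library the FPKM values of a gene are whole multiples of the value of 1 read. Whole reads were recovered on that basis for 18966 genes, all those with reads in at least 2 libraries. A gene was accepted only if its values lay within about 0.02 read of whole numbers, so the 100.0% of nonzero values within that distance follow from the rule. The largest distance was 8.94e-05 read. The recovery was tested on simulated data, where it returned 99.33% of 18547 genes. The recovered totals were 18121520 to 42486438 reads in genes per library. A gene listed at 0 may have had up to 3 reads expected in that library, by counting error alone.

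Tests used limma 3.58.1 with statmod 1.5.0 in R 4.3.3 on log2(FPKM + 1), for genes with a mean FPKM of at least 1 over the libraries in the fit, with a mean-variance trend and robust empirical Bayes, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of genes with low values. The day 16 comparison used the 6 day 16 libraries. The time comparison used all 16 libraries with a shared day factor, a line term and a line-by-day term; its coefficient is the change of the exp-minus-ctl difference over 20 days. Slopes within each line, also per 20 days, and the day 16 difference minus the day 0 difference came from further limma fits to the same libraries. The slopes of both lines came from a joint fit with a residual spread shared by the lines. The day 0 difference has 1 library per line and no test. Sdhc was also tested by an exact permutation of the line labels within days. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 40 lists, 36 had at least 3 tested members. The designs, lists and most alternatives were fixed before the data were examined.

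Named genes followed a rule fixed with the designs: the SDH subunits; at day 16 the 12 largest log2 changes per direction past the threshold with non-overlapping replicates and a mean FPKM of at least 5 in the higher group; for the time comparison the 8 largest per direction and for the other fits the 4 largest, with an FPKM of at least 5 in at least 3 libraries; and up to 4 members with the smallest p per described list. Predicted genes, RIKEN clones and small RNAs were not named. Genes outside the rule are said to be so where they appear.

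The tests were tested on simulated data with 200 changed genes among 12534 to 12567 and a dispersion of 0.01. At day 16 limma recovered 87.4% of 1.5-fold changes, 99% of 2-fold and 98.5% of 4-fold changes. It also called 25, 21 and 19 unchanged genes beside the 174, 196 and 191 changed genes recovered. For the time comparison it recovered 2.5%, 58.8% and 97.4%, or 5, 117 and 189 genes, beside 1, 10 and 21 unchanged genes. Small slope differences were mostly missed at this design, and unchanged genes made up more than the nominal 0.05 of the simulated calls in each case. The simulated libraries held no replicate sets and no difference between the lines other than in the changed genes. These shares therefore do not give the recovery in the real data.

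Alternatives were other pseudocounts and filters, median-of-ratios rescaling, quantile normalization, limma without trend and robust, each replicate and each day left out, the replicate number as a block, and other list tests. Chosen after seeing the data were limma voom on the recovered reads, a batch term for day 16 replicates 2 and 3 of both lines, fits without those replicates or without replicate 1, and the list tests without day 0. The replicate numbers come from the labels. Deviations from the group means correlated at 0.38, 0.27 and 0.33 across genes between libraries with the same number. Exp replicate 3 with ctl replicate 2 gave 0.4 and exp replicate 2 with ctl replicate 3 gave 0.21, so pairing by number was not shown within replicates 2 and 3. The main fits used no pairing, and the replicate number entered as a block only as an alternative. At day 16 the values fell into 2 sets, replicate 1 and replicates 2 and 3, and within-batch values are given for these sets.

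Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.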

Results

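Gene expression was followed for 20 days after doxycycline in 2 lines of immortalized mouse embryonic fibroblasts, in which the drug switches on a Cre recombinase. In the exp line Cre can remove both copies of Sdhc (fl/fl), and in the ctl line it can remove 1 of the 2 (fl/wt). Each line was sampled on 6 days, with 3 biological replicates at day 16 and 1 library, without a replicate of its own, at day 0, 5, 9, 12 or 20. The 16 libraries hold between 18121520 (exp day 5) and 42486438 (ctl day 16 replicate 2) reads in genes. The p-values below measure the spread between these libraries of 1 line each, and not the spread between lines of a genotype.

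Sdhc, the targeted gene, was lower in the exp line than in the ctl line at day 16. It (gene ID 66052) lies on chromosome 1 from 173057296 to 173080734 on the minus strand in mm9 and encodes a membrane anchor subunit of succinate dehydrogenase. The lines started alike, at 87.8 FPKM in exp and 90.5 in ctl at day 0. The exp line then had 54.4, 43.8 and 44.0 FPKM at days 5, 9 and 12, and the ctl line 58.6, 47.6 and 52.6. At day 16 the means were 32.0 ± 5.23 FPKM in exp and 49.4 ± 1.66 in ctl (SD, n = 3 each), and at day 20 the values were 42.5 and 54.7. The day 16 difference was -0.62 ± 0.12 log2 (SE; limma, Benjamini-Hochberg adjusted p = 0.0434), with -0.45 in the replicate 1 pair and -0.71 in replicates 2 and 3. Over days 5 to 20 the mean difference was -0.29 log2, with exp lower on 5 of 5 days (exact permutation within days, two-sided p = 0.00625, the smallest that 320 permutations allow). Without day 16 replicates 2 and 3 it was -0.26, with an exact p of 0.0625, the smallest that 32 permutations allow. Sdhc fell by 1.26 ± 0.28 log2 per 20 days in the exp line (limma adjusted p = 0.0242). The exp slope was -0.81 without day 0 (limma adjusted p = 0.297), -0.95 without day 16 (0.188) and -1.03 without day 16 replicates 2 and 3 (0.0513). The ctl slope was -0.66 ± 0.28 and the difference between the slopes, -0.60 ± 0.23, did not pass (adjusted p = 0.384).

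The day 16 call for Sdhc passed without exp replicate 1 (adjusted p = 0.0126) and was lost without any other library: 0.134 and 0.0692 without exp replicates 2 and 3, and 0.107, 0.15 and 0.146 without ctl replicates 1, 2 and 3. It was also lost with no filter on low values (0.0614) and after median-of-ratios rescaling (0.052). The mRNAs of the other subunits did not differ at day 16. Sdha, the flavoprotein, had 72.6 ± 1.42 FPKM in exp and 72.7 ± 2.05 in ctl. Sdhb, the iron-sulfur subunit, had 27.6 ± 1.07 and 27.0 ± 1.47, and Sdhd, the other membrane anchor, 94.2 ± 11.3 and 93.3 ± 3.34 (limma adjusted p = 0.987, 0.832 and 0.975; SD, n = 3). Sdhaf4, an assembly factor of the enzyme, was lower in exp by limma at -0.41 ± 0.07 log2 (adjusted p = 0.0263), from a day 0 difference of 0.73. The list of 8 SDH subunits and assembly factors had a median of 0.01 and a mean of -0.09 at day 16, with 2 members lower over all genes tested and 2 lower when adjusted over the list alone, and was not called by camera, which put it lower (adjusted p = 0.595).

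**Figure D1:**
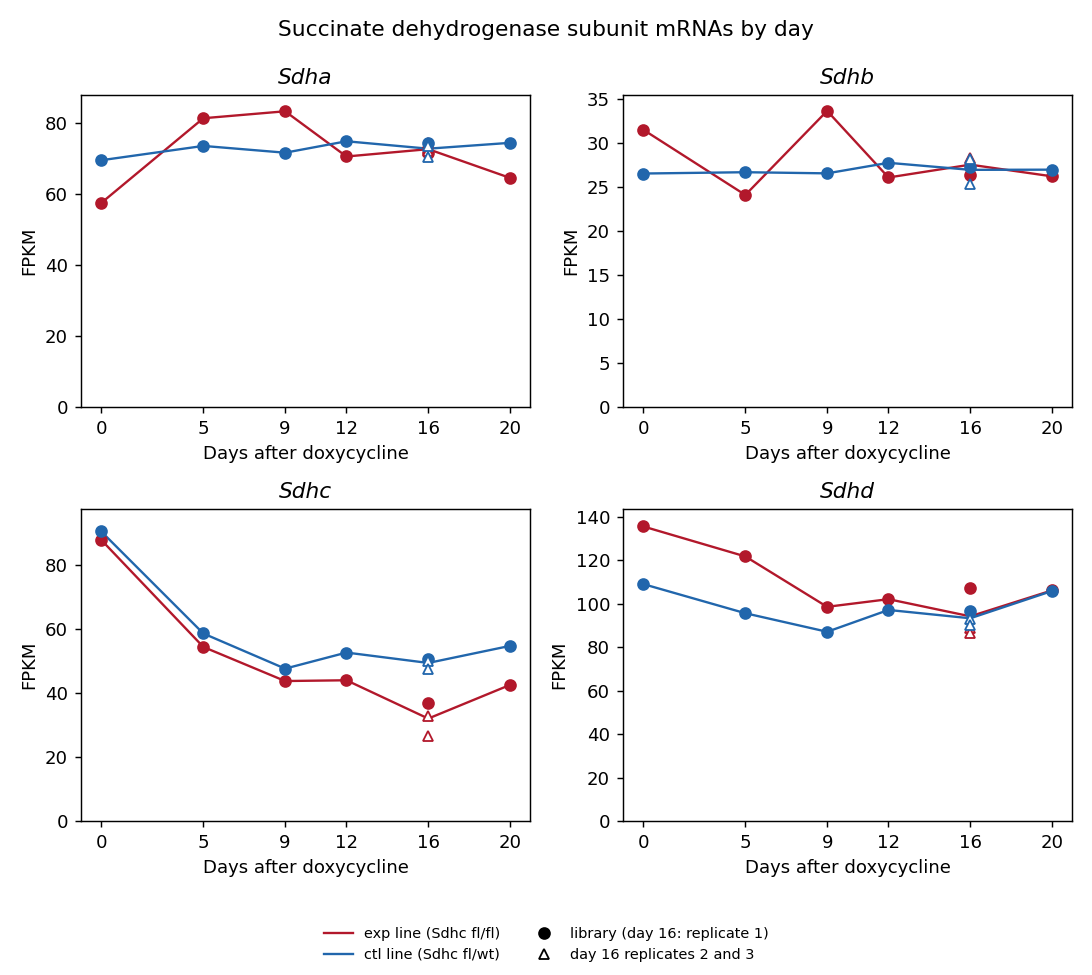
FPKM of Sdha, Sdhb, Sdhc and Sdhd (y axes, from 0) against days after doxycycline, with the exp line in red and the ctl line in blue; filled circles are single libraries or day 16 replicate 1, open triangles are day 16 replicates 2 and 3, and lines join the means per day. Sdhc declined in both lines and stood at 32.0 FPKM in exp and 49.4 in ctl at day 16, while the day 16 means of Sdha, Sdhb and Sdhd were close to each other in the lines.

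The lines differed before doxycycline. At day 0, 934 of 12640 genes differed by at least 1 log2 between the single libraries, 613 higher and 321 lower in exp, with no replicate check. The exp line expressed the Y-linked genes Ddx3y at 21.6 ± 3.05 FPKM and Eif2s3y at 26.7 ± 5.15 (SD over 8 libraries), where the ctl line had 0.0368 and 0.0435. Xist, the X-inactivation RNA, had a mean of 70.8 ± 16.9 in ctl and 0.156 in exp. The lines thus differ in sex-linked expression at every day. Across genes, the day 0 and day 16 differences correlated at r = 0.68 and rho = 0.44 (12533 genes, which are not independent replicates).

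At day 16, 765 of 12533 genes differed between the lines, 388 higher and 377 lower in exp (limma, adjusted p under 0.05). Among the largest differences, Upk3b and Upk1b, which encode uroplakins, were higher in exp by 5.80 ± 1.12 and 4.61 ± 0.87 log2. Vnn1, a pantetheinase, and Tnn, the matrix protein tenascin N, were each higher by 3.77, with SEs of 0.68 and 0.36. Gpm6a, a membrane glycoprotein, was higher by 4.56 ± 0.95 (adjusted p = 0.0485; 0.053 with a replicate block), and Lpl, lipoprotein lipase, by 3.38 ± 0.69 (0.0475; 0.0538 with the block). The intermediate filament gene Prph was higher by 2.80 ± 0.48 and the imprinted gene Peg3 by 2.74 ± 0.43, with its antisense transcript Peg3os at 3.12 ± 0.44, whose reads cannot be told apart without strand. The Y-linked Eif2s3y, Ddx3y and Kdm5d were higher by 4.68, 4.40 and 3.23.

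Lower in exp were Xist at -5.94 ± 0.21 log2 and Tsix, which overlaps it, at -4.71 ± 0.19. Several genes of embryonic patterning were lower too: Sim2 at -5.26 ± 0.12, Hoxc6 at -4.26 ± 0.21, Hoxc8 at -3.40 ± 0.18, Hoxa5 at -3.31 ± 0.14 and Alx1 at -3.19 ± 0.22. So were the secreted factors C1qtnf3 (-4.44 ± 0.43) and Wnt10a (-3.83 ± 0.31), the ubiquitin ligase gene Pdzrn3 (-3.37 ± 0.20), the kinase gene Pkdcc (-3.34 ± 0.15) and Crabp1, a retinoic acid binding protein (-3.30 ± 0.10). At day 0 Sim2 already stood at -4.92, Hoxc6 at -4.70, Crabp1 at -3.24 and Upk3b at 5.79. Of the 765 genes, 662 (86.5%) had the same sign at day 0, against 64% of all genes tested, and 193 (25.2%) had a day 0 difference under 0.25 or of the opposite sign.

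All 765 genes had the same sign in the replicate 1 pair and in replicates 2 and 3, which their selection on these 6 libraries favours. Over all genes tested the differences in the 2 sets correlated at r = 0.66 and rho = 0.51 across genes. The sizes could differ widely: Upk3b was 8.56 in replicate 1 and 4.42 in replicates 2 and 3, Upk1b 6.80 and 3.51, and Lpl 5.10 and 2.51, while Sim2 was -5.14 and -5.32. Upk3b, Upk1b, Gpm6a, Vnn1, Lpl, Prph and Peg3 lost their calls when any library other than exp replicate 1 was left out; the adjusted p then ran from 0.0745 to 0.15 for Upk3b, 0.0699 to 0.142 for Upk1b, 0.092 to 0.167 for Gpm6a, 0.0553 to 0.131 for Vnn1, 0.0849 to 0.165 for Lpl, 0.0646 to 0.131 for Prph and 0.053 to 0.102 for Peg3. With limma voom on recovered reads the differences were larger and not called, at 8.15 for Upk3b and 9.28 for Upk1b (0.253 for both), 10.2 for Gpm6a (0.282), 5.42 for Vnn1 (0.123), 8.44 for Lpl (0.173) and 3.86 for Prph (0.0682). With a pseudocount of 5 all of these genes lost their calls, at 3.84 for Upk3b (adjusted p = 0.103), 2.63 for Upk1b (0.117), 2.58 for Gpm6a (0.146), 2.16 for Vnn1 (0.0954), 1.63 for Lpl (0.148), 1.52 for Prph (0.0743), 1.26 for Peg3 (0.0713) and 1.54 for Peg3os (0.0554). With no filter on low values Upk3b stood at 0.062, Upk1b at 0.0595, Gpm6a at 0.0729, Vnn1 at 0.0551 and Lpl at 0.0713. Mean FPKM of at least 5 and quantile normalization ended the calls of Gpm6a (0.0519 in both) and Lpl (0.0521 and 0.0533). Gpm6a also lost its call after median-of-ratios rescaling (0.0504) and in limma without trend and robust (0.0512). Peg3os lost its call without ctl replicate 1, 2 or 3 (0.055, 0.0742 and 0.0778). The other 16 of the 25 genes named for this comparison and called kept theirs in each of the 6 fits without 1 library. The number of genes was 1599 without exp replicate 1, 237 and 242 without exp replicates 2 and 3, and 218 and 197 without ctl replicates 2 and 3. It was 4326 in replicates 2 and 3 alone, of which 758 were among the 765. Replicates 2 and 3 correlated at r = 0.995 in exp and 0.997 in ctl. With replicate 1 they correlated at 0.952 and 0.954 in exp and 0.979 and 0.981 in ctl. The 4326 calls thus rest on a small spread, and the fits with 3 replicates per line count these close libraries as independent.

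Interferon-stimulated genes were higher in the exp line at day 16 and rose in exp against ctl over time. Isg15, a ubiquitin-like modifier, had 78.3 ± 4.53 FPKM in exp and 12.4 ± 1.32 in ctl at day 16 (SD, n = 3), a difference of 2.57 ± 0.09 log2 (limma adjusted p = 0.000124), and 0.10 at day 0. Usp18, the protease that removes Isg15, had 9.31 ± 0.824 and 1.43 ± 0.197 (2.08 ± 0.10). Oas1a, an oligoadenylate synthetase, differed by 1.83 ± 0.10 and Ifih1, a sensor of double-stranded RNA, by 1.49 ± 0.08. Of 27 list members tested, 22 were higher at day 16 over all genes tested and 26 when adjusted over the list alone, with a median of 1.14 (camera adjusted p = 1.66e-24). That call was lost with adjusted p = 0.538 with an estimated correlation. Within batches, Isg15 differed by 2.47 in the replicate 1 pair and 2.62 in replicates 2 and 3, and Usp18 by 1.93 and 2.16.

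Over time, the median exp-minus-ctl difference of the 26 list members in the slope fit was -0.17 at day 0, -0.23 at day 5, 0.43 at day 9 and 0.80 at day 12. At day 16 it was 1.06, 1.34 and 1.19 in replicates 1, 2 and 3, and at day 20 it was 1.06. The slope difference was 3.16 ± 0.33 log2 per 20 days for Usp18 (limma adjusted p = 0.00937), 3.14 ± 0.41 for Oasl2, 2.93 ± 0.38 for Isg15 and 2.34 ± 0.25 for Oas1a. Bst2, which tethers virus particles to the cell surface, had 2.68 ± 0.37. In the ctl line the Isg15 and Usp18 slopes were -0.80 ± 0.32 and -0.85 ± 0.28, neither past the threshold. Of the 26 members, 9 rose over all genes tested and 23 when adjusted over the list alone, with a median slope difference of 1.83 (camera adjusted p = 1.01e-44; adjusted p = 0.0402 with an estimated correlation). Outside the list, Lgals3bp (2.63 ± 0.32), Rtp4 (2.54 ± 0.38; adjusted p = 0.0301, and 0.053 with a replicate block), Irgm2 (2.42 ± 0.38) and H2-Q4 (2.44 ± 0.32) also rose. H2-Q4 is a class I histocompatibility gene with close paralogs, so its reads may be shared with them. At day 16 it differed by 0.34 in the replicate 1 pair and 0.64 in replicates 2 and 3. Irgm2 differed by 0.76 and 1.12. These differences are smaller than those of Isg15 and Usp18 at day 16, so the slopes of H2-Q4 and Irgm2 do not show an excess over ctl of that size.

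**Figure D2:**
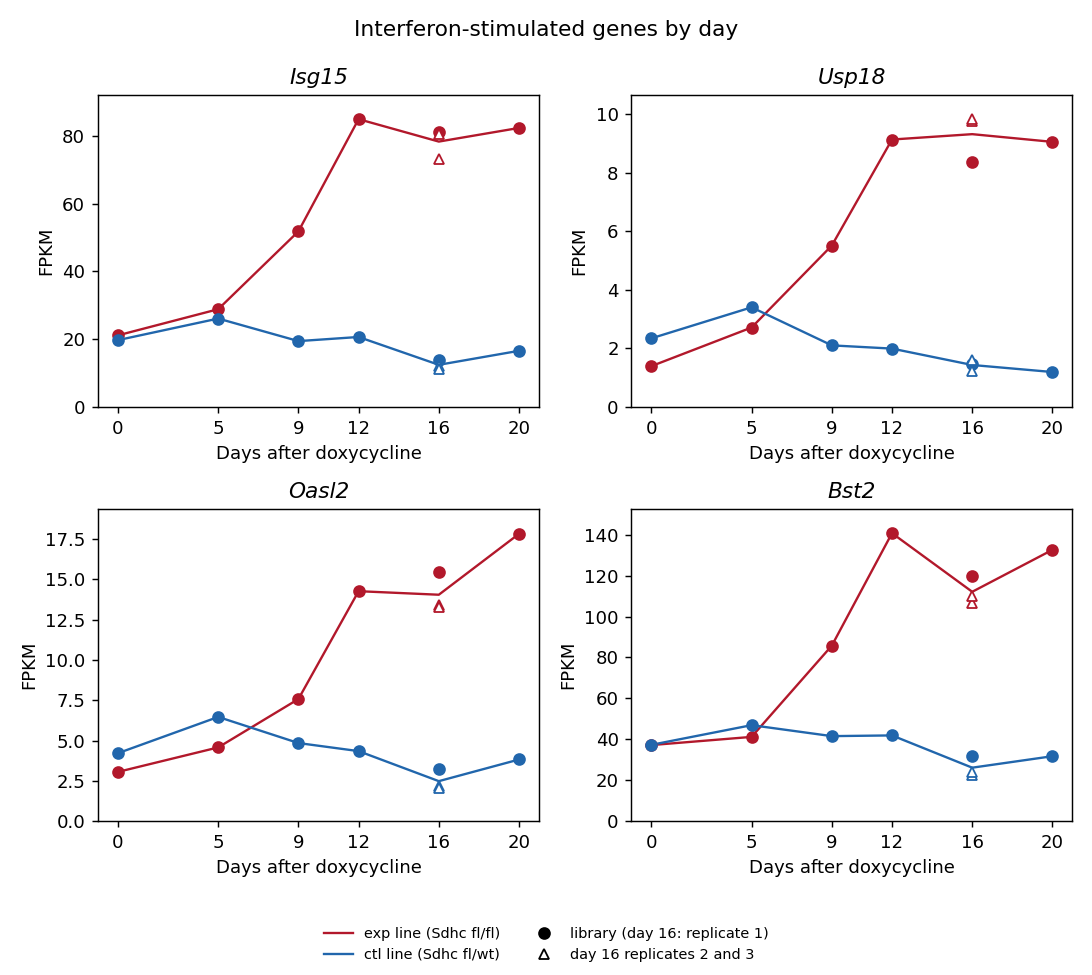
FPKM of Isg15, Usp18, Oasl2 and Bst2 (y axes, from 0) against days after doxycycline, with exp in red and ctl in blue; filled circles are single libraries or day 16 replicate 1, open triangles are day 16 replicates 2 and 3, and lines join the means per day. Isg15 reached 78.3 FPKM in exp at day 16 against 12.4 in ctl.

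In all, 26 of 12559 genes had a slope that differed between the lines, 23 upward and 3 downward in exp (limma; 1388 at an unadjusted p under 0.05). The 3 that fell were Bnip3, a mitophagy receptor (-1.31 ± 0.21 log2 per 20 days, adjusted p = 0.0373), Fam162a, a mitochondrial protein induced by hypoxia (-1.23 ± 0.16, 0.0195), and Tmem242, a mitochondrial membrane protein (-0.75 ± 0.12, 0.0409; 0.0537 with a replicate block). They started higher in exp, by 0.84, 0.83 and 0.44 at day 0, and their day 16 differences of -0.32, -0.26 and -0.16 did not pass. Bnip3 belongs to the list of 32 HIF targets, of which it alone fell, also when adjusted over the list alone, and which was not called (median -0.16, camera adjusted p = 0.32).

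The slope count moved when libraries were left out. It was 2, 10, 12 and 7 without exp replicate 2, exp replicate 3, ctl replicate 2 and ctl replicate 3, and 1, 8, 14, 12 and 0 without days 0, 5, 9, 12 and 16. With the day 16 replicates averaged it was 0, with an adjusted p of 0.126 to 0.166 for the named genes. Without day 16 replicates 2 and 3 all 11 named genes lost their calls (0.059 to 0.114). Of the 11 genes named for this comparison, Usp18 alone kept its call in each fit without 1 replicate; without exp replicate 2, Isg15, Oasl2, Lgals3bp, H2-Q4 and Fam162a stood at 0.0537, Bst2 at 0.0658, Rtp4 at 0.0674, Irgm2 at 0.0704, Bnip3 at 0.0674 and Tmem242 at 0.0709. Other single replicates gave 0.0512 to 0.0688 for Rtp4, 0.0614 and 0.0618 for Bst2, 0.0531 for H2-Q4 (ctl replicate 3), 0.0624 to 0.0688 for Irgm2, 0.0531 to 0.098 for Bnip3 and 0.0627 to 0.105 for Tmem242. All 11 calls were lost without day 0, while the slope differences stood at 3.25 for Usp18, 3.63 for Oasl2, 3.14 for Isg15, 2.95 for H2-Q4, 3.06 for Bst2, 2.77 for Rtp4, 2.55 for Irgm2, 2.45 for Lgals3bp, -1.17 for Bnip3, -1.11 for Fam162a and -0.65 for Tmem242 (adjusted p = 0.105 for Usp18 and H2-Q4, 0.11 for Oasl2, 0.144 for Isg15 and Bst2, 0.203 for Lgals3bp, 0.24 for Rtp4 and Fam162a, 0.285 for Irgm2, 0.479 for Bnip3, 0.504 for Tmem242). All were also lost without day 16 (0.164 to 0.257). Leaving out day 5, 9, 12 or 20 also ended the calls of Bnip3 (0.0591 to 0.0893) and Tmem242 (0.0666 to 0.124), and day 5 that of Fam162a (0.0624) and Oasl2 (0.0533). Day 9 ended that of Bst2 (0.0513), and days 5, 9 and 12 those of Rtp4 (0.0864, 0.0663 and 0.0513) and Irgm2 (0.0864, 0.0716 and 0.0623). With no filter Rtp4 stood at 0.0604 and Irgm2 and Bnip3 at 0.0631. With no day factor Irgm2 stood at 0.0744, Fam162a at 0.0543 and Tmem242 at 0.184. Tmem242 also lost its call after median-of-ratios rescaling (0.0648) and with limma voom on recovered reads (0.0576). The median of the interferon list without day 0 was 2.18.

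**Figure D3:**
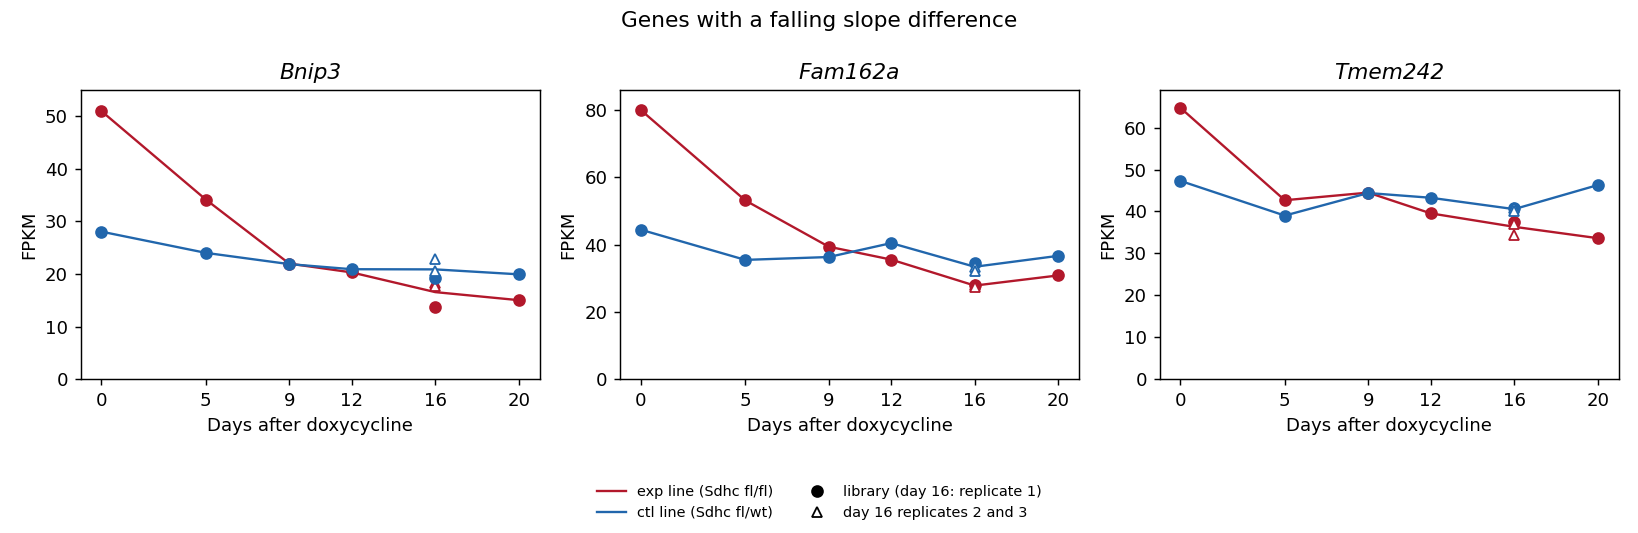
FPKM of Bnip3, Fam162a and Tmem242 (y axes, from 0) against days after doxycycline, with exp in red and ctl in blue; filled circles are single libraries or day 16 replicate 1, open triangles are day 16 replicates 2 and 3, and lines join the means per day. Each gene started higher in exp, by 0.84, 0.83 and 0.44 log2 in this order, and ended near or below ctl.

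Extracellular matrix genes rose as a list in the exp line against ctl over time. The median slope difference over 38 members was 0.66 (camera adjusted p = 7.71e-15; adjusted p = 0.00174 with an estimated correlation), with 36 of 38 positive. No member passed over all genes tested in limma, and 7 rose when adjusted over the list alone. The collagen gene Col8a1 had a slope difference of 1.43 ± 0.25, tenascin C (Tnc) 1.40 ± 0.26, Col1a1 0.66 ± 0.16 and fibulin 2 (Fbln2) 0.78 ± 0.21 (adjusted p = 0.0556, 0.0666, 0.138 and 0.216). At day 16 the list had a median of 0.30, with 5 members higher and 1 lower over all genes tested and 10 and 4 when adjusted over the list alone. Col1a2, a chain of type I collagen, was higher by 2.72 ± 0.13 (2.11 at day 0), Tnc by 1.06 ± 0.11 and Bgn by 0.31 ± 0.05, and the crosslinking enzyme gene Lox was lower at -0.36 ± 0.07. The matrix median was 0.31 in replicate 1 and 0.17 and 0.24 in replicates 2 and 3. The day 16 call (camera adjusted p = 0.0377) was lost with adjusted p = 0.551 with an estimated correlation, after median-of-ratios rescaling (0.0539), and without ctl replicate 1 (0.0668) or 3 (0.0568).

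Respiratory chain genes fell as lists in exp against ctl over time. For 37 nuclear-encoded complex I genes the median slope difference was -0.43 (camera adjusted p = 2.08e-09; adjusted p = 0.148 with an estimated correlation). No member passed over all genes tested, and 10 were lower when adjusted over the list alone; Ndufb8 had -0.87 ± 0.19 and Ndufs4 -0.70 ± 0.16 (limma adjusted p = 0.108 and 0.116). Complexes III, IV and V had a median of -0.36 over 35 genes (3.42e-06; adjusted p = 0.183 with an estimated correlation), with 3 lower when adjusted over the list alone, and 0.102 without day 0; Uqcrh had -0.91 ± 0.19. The mitochondrial ribosome list had -0.25 over 38 genes (7.01e-06; adjusted p = 0.183 with an estimated correlation; 3 lower when adjusted over the list alone), and Mrpl18 had -0.66 ± 0.12. The SDH list had -0.42 over 8 genes (0.000854; adjusted p = 0.0535 with an estimated correlation; 3 lower when adjusted over the list alone), and Sdhaf4 had -1.11 ± 0.22. Among 10000 random lists matched on length and expression, the complex I median lay at percentile 4.79 (median of the matched lists -0.31), complexes III, IV and V at 19.3 (-0.30), the mitochondrial ribosome at 40.57 (-0.23) and the SDH list at 6.16 (-0.22). At day 0 the exp library also stood above ctl for cytosolic ribosomal proteins (median 0.48, 36 of 37 higher) and histones without poly(A) tails (1.16, 17 of 17). The complex I difference was 0.54 at day 0 and between -0.01 and 0.22 at later days, and without day 0 the median slope difference was -0.18. Without day 0 the calls of complex I (adjusted p = 0.00322), the mitochondrial ribosome (0.00573; median -0.19) and the SDH list (0.00033; median -0.48) passed.

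Other lists called over time had no member past the test over all genes. The 32 genes of the ATF4 and amino-acid response had a median of 0.19 (camera adjusted p = 0.000854; adjusted p = 0.587 with an estimated correlation), 0 of them passing when adjusted over the list alone, and 0.374 without day 0. For 14 fibroblast markers it was 0.48 (0.0315; adjusted p = 0.17 with an estimated correlation), with 2 higher and 1 lower when adjusted over the list alone, and 0.484 without day 0, 0.0605 after median-of-ratios rescaling and 0.0798 with mean FPKM of at least 5. The 37 cytosolic ribosomal protein genes had -0.29 (0.00182; adjusted p = 0.618 with an estimated correlation) and 17 histone genes whose mRNAs lack poly(A) tails had -0.64 (0.00177; adjusted p = 0.587 with an estimated correlation). Both turned positive without day 0, at 0.10 and 0.19, where neither was called (0.754 and 0.41), and the histone call was lost with mean FPKM of at least 5 (0.102). DNA replication and mitosis genes had -0.17 over 35 genes (0.035; adjusted p = 0.643 with an estimated correlation), and the call was lost without exp replicate 2 (0.128), exp replicate 3 (0.0994), ctl replicate 2 (0.0787) and ctl replicate 3 (0.0746), after median-of-ratios rescaling (0.0643) or quantile normalization (0.206), and with a batch term for day 16 replicates 2 and 3 (0.873) or without these replicates (0.901). In the ribosomal, histone and DNA replication lists 0 members passed when adjusted over the list alone. The other 25 of the 36 lists were not called, with medians from -0.37 to 0.77.

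At day 16, genes of the ATF4 and amino-acid response were higher in exp as a list, with a median of 0.43 over 32 genes and 32 of 32 positive. Atf4 itself differed by 0.55 ± 0.11, and the amino acid transporter genes Slc7a5 and Slc3a2 by 0.78 ± 0.13 and 0.58 ± 0.11 (limma adjusted p = 0.0427, 0.0276 and 0.0378). These 3 passed over all genes tested and 14 when adjusted over the list alone (camera adjusted p = 1.92e-10; adjusted p = 0.578 with an estimated correlation). The median was 0.55 in replicate 1 and 0.35 and 0.46 in replicates 2 and 3. The day 0 difference of Atf4 was already 0.44. Cholesterol biosynthesis genes had a median of 0.36, with 23 of 23 positive and 0 passing over all genes or when adjusted over the list alone (9.9e-05; adjusted p = 0.625 with an estimated correlation), and 0.46 at day 0, 0.55 in day 16 replicate 1 and 0.18 and 0.25 in replicates 2 and 3; Mvd had 0.50 ± 0.11 and Sqle 0.49 ± 0.12.

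Smaller lists were called at day 16. Of 7 smooth-muscle and myogenic markers, Acta2 was higher by 1.34 ± 0.26, and 4 were higher when adjusted over the list alone (median 1.05, camera adjusted p = 0.00471; adjusted p = 0.551 with an estimated correlation). The median was 0.78 in replicate 1 and 1.47 and 1.12 in replicates 2 and 3, and with no filter on low values the camera adjusted p was 0.116. At day 0 the smooth-muscle median was already 0.85, with 7 of 7 higher in exp, and at day 20 it was 0.10, with 4 of 7 higher. Of 4 chromaffin and sympathetic markers, the transcription factor genes Gata2 (0.87 ± 0.08) and Hand2 (1.87 ± 0.37) were higher, also when adjusted over the list alone (2 genes; median 0.61, 0.0148; adjusted p = 0.551 with an estimated correlation); at day 0 they differed by 0.99 and 1.71, and without replicate 1 in both lines the adjusted p was 0.0606. The chromaffin median was 0.87 in replicate 1 and 0.39 and 0.59 in replicates 2 and 3. Of 6 adipocyte markers, Lpl and Cebpa (0.87 ± 0.18) were higher, and 3 when adjusted over the list alone (median 0.65, 0.0487; 0.0579 with a replicate block; adjusted p = 0.551 with an estimated correlation). Their median was 0.31 in replicate 1 and 1.28 and 1.05 in replicates 2 and 3. Of 23 demethylases that use 2-oxoglutarate, the X-linked Kdm5c (-0.55 ± 0.07) and Kdm6a (-0.47 ± 0.07) were lower, and 3 when adjusted over the list alone. The list median was -0.10 (camera adjusted p = 0.0487, 0.056 with a replicate block and 0.625 with an estimated correlation), with -0.15 in replicate 1 and -0.07 in both others. At day 0 the demethylase median was already -0.2, with 7 of 23 higher in exp, and at days 5 and 12 it was -0.2 and 0.07. Sex-linked expression differs between the lines, so the 2 X-linked genes cannot be tied to Sdhc.

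Fatty acid oxidation had a median of -0.13 over 21 genes, with Cpt1a lower at -0.45 ± 0.07, the only member past the test, also when adjusted over the list alone (camera adjusted p = 0.0487; adjusted p = 0.625 with an estimated correlation). The p53 targets had 0.16 over 22 genes (0.0487; adjusted p = 0.625 with an estimated correlation); the kinase gene Plk2 was lower at -0.86 ± 0.16, against the direction of the list, and 1 gene was higher and 1 lower when adjusted over the list alone. DNA replication and mitosis had -0.09 over 35 genes, 0 passing over all genes or when adjusted over the list alone (0.0377; adjusted p = 0.653 with an estimated correlation). The DNA replication median was 0.02 in replicate 1, with 19 of 35 genes higher, and -0.17 and -0.14 in replicates 2 and 3, with 4 and 3 higher, so the direction was not seen in replicate 1. In the same order the medians were 0.05, 0.34 and 0.19 for the p53 targets and -0.21, -0.04 and -0.10 for fatty acid oxidation. The calls of these 3 lists and of the adipocyte and demethylase lists were each lost without at least 3 of the 6 libraries taken singly. Without exp replicate 2 the adjusted p was 0.0681 for fatty acid oxidation and the adipocyte markers, 0.17 for the p53 targets and DNA replication, and 0.11 for the demethylases. Over the other libraries whose loss ended a call it was 0.0533 to 0.147 for fatty acid oxidation (exp 1, exp 3, ctl 1), 0.0516 to 0.0754 for the p53 targets (exp 3, ctl 1 to 3), 0.075 to 0.0988 for DNA replication (exp 3, ctl 2, ctl 3), 0.0599 to 0.0754 for the adipocyte markers (exp 3, ctl 1 to 3), and 0.0542 and 0.147 for the demethylases (exp 3, ctl 1). Median-of-ratios rescaling ended these 5 calls (0.0539 each), as did quantile normalization (0.0502 to 0.0732). With no filter the adipocyte markers stood at 0.473. With mean FPKM of at least 5 the adipocyte markers stood at 0.0587, the p53 targets at 0.0623 and fatty acid oxidation at 0.0513. Without replicate 1 in both lines fatty acid oxidation stood at 0.137 and the demethylases at 0.143. With a batch term the demethylases and adipocyte markers stood at 0.052 and 0.0592. With pseudocounts of 5 and 0.1 the adipocyte markers and p53 targets stood at 0.0587 and 0.0511. The other 25 lists, glycolysis (median -0.14, adjusted p = 0.095) and HIF targets (-0.12, 0.131) among them, were not called. With an estimated correlation 0 of the 36 lists were called at day 16 and 2 over time, the interferon and matrix lists. Lists were also tested by fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. Its day 16 adjusted p was 0.0922 for the ATF4 list, 0.212 for cholesterol biosynthesis and DNA replication, 0.0822 for the smooth-muscle markers and demethylases, 0.131 for fatty acid oxidation and 0.16 for the p53 targets. None of these passed, while the interferon (0.00118), matrix (0.000503), chromaffin and adipocyte (0.0402 each) lists did. Over time fry gave 0.637 for the ATF4 list, 0.396 for the cytosolic ribosomal and DNA replication lists, 0.309 for histones and 0.164 for fibroblast markers. The other 6 lists called by camera passed.

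Within the exp line, 622 genes changed over the 20 days, 171 upward and 451 downward (limma). Igfbp3, an insulin-like growth factor binding protein, rose by 2.93 ± 0.46 log2, Dlk1, an imprinted growth regulator, by 2.73 ± 0.70, elastin (Eln) by 2.68 ± 0.53 and Oasl2 by 2.35 ± 0.32 (adjusted p = 0.00552, 0.0409, 0.0182 and 0.00339). The immediate-early genes Fosb and Fos fell by 5.96 ± 1.28 and 4.29 ± 0.95, and Zfp36 and Dusp1 fell by 2.62 ± 0.57 and 2.61 ± 0.62. In the ctl line 0 genes passed in limma (203 at an unadjusted p under 0.05, and 0 with limma voom). The ctl slopes were -6.45 ± 1.28 for Fosb and -5.85 ± 0.95 for Fos. Both lines' slopes came from a joint fit with a shared residual spread, so scatter in exp also enters the error of the ctl slopes. The counts of 622 and 0 therefore do not show that ctl was unchanged. The slopes of Fos and Fosb did not differ between the lines (limma adjusted p = 0.729 and 0.946). The split of the exp genes moved with scaling: 171 of 622 were upward as deposited, 59.1% after median-of-ratios rescaling (243 upward, 168 downward) and 51.3% after quantile normalization (263 and 250), which shifted the median of all genes by 0.096 and 0.091. The exp count was 9 without day 0, 7 of them among the 622, and 1381, 371 and 72 without days 5, 12 and 16, and 249, 303, 289 and 366 without exp replicates 1, 2 and 3 and ctl replicate 1. Without day 0 the exp slope was 3.51 for Dlk1 (limma adjusted p = 0.196), 2.96 for Eln (0.161) and 2.28 for Oasl2 (0.0868). It was -4.12 for Fosb (0.349), -3.08 for Fos (0.354), -1.11 for Zfp36 (0.447) and -0.74 for Dusp1 (0.55). Without day 20 the adjusted p was 0.128 for Dlk1, 0.0504 for Eln, 0.0573 for Fosb and 0.0707 for Fos. Without day 16 the adjusted p was 0.0959 for Zfp36 and 0.11 for Dusp1. Dlk1 also lost its call without exp replicate 1 (0.0767), ctl replicates 1, 2 and 3 (0.0569, 0.0511 and 0.0522) and days 5 and 9 (0.071 and 0.0686) with a pseudocount of 5 (1.82, 0.0531), no filter (0.0568) and limma voom (0.0727), and Dusp1 without exp replicates 1 and 3 (0.0571 and 0.0557).

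The day 16 difference minus the day 0 difference passed for 0 genes in limma (1878 at an unadjusted p under 0.05, smallest adjusted p = 0.0922; 0 with limma voom), with 1 library per line at day 0. It was 355 without exp replicate 1.

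The day 16 replicates of both lines fell into 2 sets. Between replicate 1 and the mean of replicates 2 and 3, 630 genes differed by at least 2-fold in exp and 205 in ctl, against 24 and 12 between replicates 2 and 3. Upk3b had 455 FPKM in exp replicate 1 and 22.9 and 28.0 in replicates 2 and 3, and 433 at day 20. For the epithelial markers the median difference of replicates 2 and 3 from replicate 1 was -2.64 log2 in exp and -0.08 in ctl; the list was not called at day 16 (median 1.86 over 5 genes, camera adjusted p = 0.115).

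**Figure D4:**
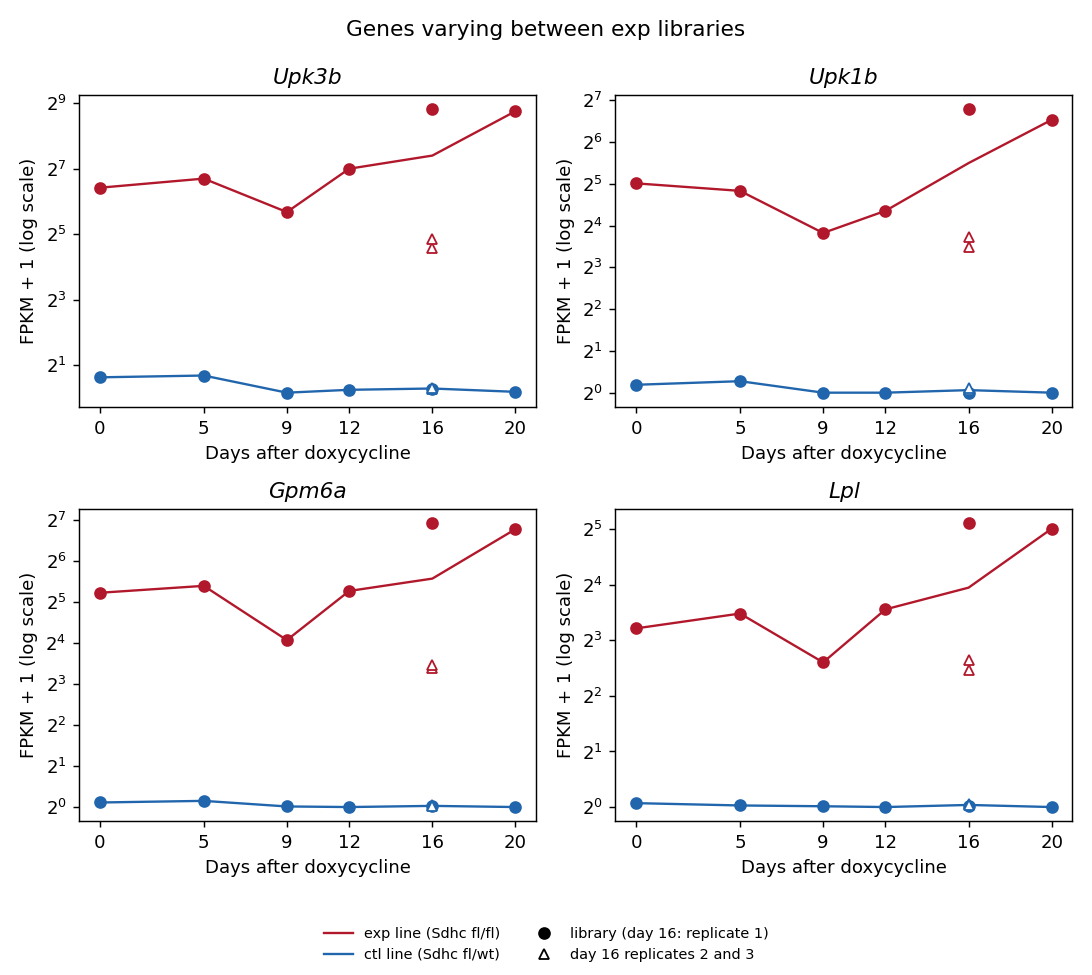
FPKM + 1 on a log axis for Upk3b, Upk1b, Gpm6a and Lpl against days after doxycycline, with exp in red and ctl in blue; filled circles are single libraries or day 16 replicate 1, open triangles are day 16 replicates 2 and 3, and lines join the means per day. Exp replicates 2 and 3 lie below exp replicate 1 at day 16, for Upk3b at 22.9 and 28.0 FPKM against 455.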

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

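The day 16 test by limma and the slope tests by limma and camera on all libraries were planned. So was the slope fit with the day 16 replicates averaged. Of the other tests below, all but the length and expression test of complex I and the length and GC test of the replicates were chosen only after the result was seen.

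For 26 genes the slope over time differed between the lines by limma's test of the line by day term. Those named are Usp18 (3.16 log2 per 20 days), Oasl2 (3.14), Isg15 (2.93), Bst2 (2.68), Lgals3bp (2.63), Rtp4 (2.54), H2-Q4 (2.44), Irgm2 (2.42), Bnip3 (-1.31), Fam162a (-1.23) and Tmem242 (-0.75). By camera, the slopes differed for the lists of interferon-stimulated genes (median 1.83), extracellular matrix (0.66), fibroblast markers (0.48), the ATF4 and amino-acid response (0.19), DNA replication and mitosis (-0.17), the mitochondrial ribosome (-0.25), cytosolic ribosomal proteins (-0.29), complexes III, IV and V (-0.36), SDH subunits and assembly factors (-0.42), complex I (-0.43) and histones without poly(A) tails (-0.64). After line and day effects were removed, the remaining values were exchanged between the lines by day, with day 16 replicate 1 and replicates 2 and 3 kept as whole sets. Of 64 such exchanges 2 gave 26 or more genes, the real order and the exchange of day 12 alone, which gave 35. That share is under 0.05, but the exchange of day 12 alone gave more genes than the real order, so chance is not excluded. At an unadjusted p under 0.05, 10 of the 64 reached the 1388 genes. The count was 0 with the day 16 replicates averaged. For the 765 genes at day 16, 1 of 10 splits, the real one, gave as many, and the splits of 6 libraries are too few for a share under 0.05. The highest of the others, those that part all 3 pairs of same-numbered libraries included, gave 0. Each of the others puts libraries of both lines in both groups. The difference between the lines then widens the spread within groups and favours low counts, so the 0 does not bear on chance.

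The interferon-stimulated genes rose in exp against ctl. Doxycycline or culture time alone would raise them in ctl too, where the median slope was -0.51. A difference already present between the lines would show at day 0, where the median was -0.17. Blood cells in the exp cultures would bring leukocyte transcripts, whose median difference over 8 genes was 0. A response to the loss of Sdhc remains as a hypothesis, and it cannot be separated from other properties of the exp line, such as its sex-linked expression, because each genotype is 1 line.

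The respiratory chain genes fell in exp against ctl over time. Lists matched to complex I on gene length and expression had a median of -0.31, and complex I, at -0.43, lay at percentile 4.79 of 10000 of them, so an effect of length and expression could account for most of the fall; complexes III, IV and V, the mitochondrial ribosome and the SDH list lay at percentiles 19.3, 40.57 and 6.16 (matched medians -0.30, -0.23 and -0.22). The exp-minus-ctl difference correlated with gene length across genes at day 0 (rho -0.33, genes not being independent replicates) and between -0.11 and 0.09 at the other libraries. Without day 0 the complex I median was -0.18 (camera adjusted p = 0.00322). It was -0.12 for complexes III, IV and V (0.102), -0.19 for the mitochondrial ribosome (0.00573) and -0.48 for the SDH list (0.00033). The SDH list thus passed without day 0, but the targeted Sdhc is among its members. In exp the complex I median stood at -0.57 from its own day 0 by day 5, at -0.16 at day 9 and at -0.52 at day 20. Much of the fall was thus a step from the single exp day 0 library, and how much the day 0 libraries carry stays open for complex I. A response to Sdhc loss was not separated from an effect of length and expression or of the day 0 libraries.

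Day 16 replicates 2 and 3 stood apart from replicate 1 in both lines. Sequencing depth was argued against over 6214 genes with at least 1000 reads in each day 16 library of both lines, where counting error is small. In exp their median distance from replicate 1 was 2.99 times that between replicates 2 and 3 (3.48 times in ctl). Gene length and GC content explained at most 7.08% of the variance. Exp day 20 correlated at 0.993 with exp day 16 replicate 1 and at 0.952 and 0.954 with replicates 2 and 3. In ctl these values were 0.996, 0.98 and 0.982. The main slope fits hold no term for the shift of replicates 2 and 3, which exist only at day 16. The shifts of the lines correlated at 0.38 across genes, so a change shared by both lines, such as a separate culture or library batch, stays open. In exp a varying share of mesothelial-like cells stays open too, since the 7 further markers that followed had been seen to vary together before that was tested; no explanation by Sdhc genotype was tested.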

How the results depend on the processing

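Chosen only after the data were seen were limma voom, the batch term, the fits without day 16 replicates 2 and 3 or without replicate 1 in both lines, and the list tests without day 0. The number of genes differing at day 16 (765) was 493 with mean FPKM of at least 5, 2618 with a batch term for replicates 2 and 3, 4326 without replicate 1 in both lines, and 197 to 1599 leaving out 1 replicate. The slope count (26) was 49 after quantile normalization, 296 with the batch term, 1, 8, 14, 12 and 0 without days 0, 5, 9, 12 and 16, 2 without day 16 replicates 2 and 3 (0 of them among the 26), 0 with these replicates averaged, and 2 to 35 leaving out 1 replicate. Day 16 minus day 0 (0 in limma; 1878 unadjusted, 0 with voom) gave 93 with no filter, 1204 with the batch term and 0 to 355 leaving out 1 replicate. The exp slope (622) gave 411 after median-of-ratios rescaling, 1902 with the batch term, 9, 1381, 371 and 72 without days 0, 5, 12 and 16, and 249 to 466 leaving out 1 replicate. The ctl slope (0 in limma; 203 unadjusted, 0 with voom) gave 1 with the batch term, 1 without day 16 replicates 2 and 3, and 0 to 2 leaving out 1 replicate. Lists called at day 16 (11) were 5 after median-of-ratios rescaling, 6 after quantile normalization, 0 with an estimated correlation, 5 by fry and 6 to 14 leaving out 1 replicate. Over time (11) they were 2 with an estimated correlation and 6 by fry. Day 0 differences of at least 1 log2 (934) were 379 with a pseudocount of 5 and 533 with mean FPKM of at least 5. Sdhc over days 5 to 20 was -0.26 without day 16 replicates 2 and 3. Without day 0, cytosolic ribosomal proteins and histones turned positive (adjusted p = 0.754 and 0.41). Fewer libraries or genes enter by construction where they were left out; otherwise the cause was not tested.

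Replicate numbers were checked for pairing: same-numbered libraries correlated at 0.38, 0.27 and 0.33. Exp replicate 3 with ctl replicate 2 gave 0.4 and exp replicate 2 with ctl replicate 3 gave 0.21. Pairing by number was thus not shown within replicates 2 and 3. With a replicate block, 1023 genes differed at day 16 (611 of the 765 among them), 37 over time (21 of the 26) and 0 for day 16 minus day 0; 11 lists were called at day 16 (9 of the 11 without it) and 12 over time (11 of the 11). Among named results the block changed no call other than those of Gpm6a, Lpl, Rtp4, Tmem242, the adipocyte markers and the demethylases. Of the single genes and lists named, 1433 values under an alternative kept their side of the threshold, 292 lost the call, 1 gained it and 2 turned to the other direction. Any uncalled values that changed direction are counted among the 1433. Depth limits the low genes. In the smallest library, exp day 5 at 18121520 reads, Nkain4, a gene outside the naming rule, had 26 reads at 1.51 FPKM.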

Other observations

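The mesothelial and imprinted lists below were written after some of their genes had been noticed, and both tests were chosen only after results over the whole lists had been seen, so neither can bear out its explanation.

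Immediate-early genes were higher at the start in the exp line. Their median exp-minus-ctl difference over 20 genes was 0.87 log2 at day 0, and from their own day 0 they stood at -2.07 in exp and -0.75 in ctl at day 5, from single libraries without a test. The median difference was -0.22 at day 5, the lowest of the days, and between 0.02 and 0.56 at the later libraries. Among HIF targets, which were not called as a list, Car12, a membrane carbonic anhydrase, was lower in exp at day 16 by limma (-2.00 ± 0.31 log2, adjusted p = 0.0216). The epithelial keratin gene Krt14 had 40.6 FPKM in exp and 0.0906 in ctl at day 16 and did not pass (limma adjusted p = 0.0735).

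Genes of mesothelial cells varied between the exp libraries. Upk3b had 84.9, 103, 50.3 and 127 FPKM at days 0, 5, 9 and 12, then 455 in day 16 replicate 1, 22.9 and 28.0 in replicates 2 and 3, and 433 at day 20. A varying share of mesothelial-like cells in the exp cultures is a candidate explanation. It predicts that other mesothelial markers follow, and the 7 other markers listed and found (Msln, Lrrn4, Krt7, Krt18, Krt19, Nkain4 and Bnc1) were at least 2-fold higher in exp replicate 1 and day 20 than in replicates 2 and 3. Because the joint variation of the listed markers had been seen before this comparison was chosen, mesothelial-like cells at a varying share stay open as an explanation. For Lrrn4 the lowest of the former was 147 FPKM and the highest of the latter 11.2, and for Krt18 31.9 and 2.27. Of 13 genes listed 12 were found, and 4 of them had a mean of at least 1 FPKM in ctl as well. Msln was among these, with 84.8 to 121 FPKM over the ctl libraries, above the 15.3 and 20.7 of exp replicates 2 and 3, so it does not mark the exp line.

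Imprinted growth genes rose within the exp line: Dlk1 by 2.73 log2 per 20 days, Mest by 1.93, Plagl1 by 1.71, Igf2 by 1.20 and Grb10 by 0.68, which makes 5 of 18 tested; 0 passed downward, and 5 of the 18 had a slope below 0 without passing. Dlk1 lost its call in 11 of 23 alternatives, and without day 0 the exp count was 9 genes, 7 of them among the 622. A shared rise of imprinted genes may underlie this and stays open. Over the 14 members other than those noticed first, of which 2 rose, the median exp slope was 0.15 (camera with an estimated correlation, p = 0.0276), but the slopes of these members had been seen before that test was chosen. Over all 18 the median was 0.26 in exp and 0.04 in ctl. At day 16 several stood lower in exp than in ctl by limma: Dlk1 at -2.62, H19 at -2.39, Igf2 at -2.33, Peg10 at -1.67, Meg3 at -1.62 and Grb10 at -1.43 (adjusted p = 0.0495, 0.0277, 0.00477, 0.0224, 0.011 and 0.00145), while Peg3 was higher.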
